A study of Rattus norvegicus with 3 samples.

How the data were processed

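The series holds RNA sequencing of motor cortex from 3 male Sprague-Dawley rats that received electroacupuncture at the GB20 (Fengchi) point after cerebral ischemia and reperfusion. The labels give each animal a number (12, 24-4 and 33) and a time of 8 weeks, without saying what the time is counted from. All 3 rats belong to 1 group. Sham, untreated and unstimulated animals were not analysed here, so no effect of ischemia or of acupuncture was tested. The rats are biological replicates, 1 library each.

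The deposited values are FPKM, fragments per kilobase of gene per 1000000 fragments. Per the labels' protocols, total RNA was checked for integrity, mRNA was separated and fragmented, and double-stranded cDNA was made into libraries. Per the series' design text, the authors counted fragments per gene, normalized the counts and computed FPKM with a script. HISAT2 (version 2.0.4) and StringTie (version 1.3.0) and the genome build Rnor_6.0 are named in the submitters' processing notes. The kind of normalization, and whether counting used the strand, are not given in the sources used here. FPKM is relative to the whole library, so an abundant transcript in 1 library lowers every other value in it. Coordinates are those in the deposited files, on Rnor_6.0. An annotation table of assembly GRCr8 served only to match gene symbols. GC content could not be checked, because no genome sequence was used here.

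Each file listed 30957 genes, of which 11974 were listed at 0 in all 3 rats. Genes that every cell uses, such as Hprt1, Rps6, Rpl8 and Hsp90aa1, were among them, so a 0 can be a failed estimate. Such genes are described only as listed at 0. No pair of files held equal values throughout. Depth was estimated from loci of at most 400 bp, whose low values are whole multiples of what 1 fragment is worth. The estimates were 15350000 fragments for rat 12, 17260000 for rat 24-4 and 13020000 for rat 33. With a tolerance of 0.02, 91.2% of 690 values, 91.1% of 676 and 91.9% of 717 came out whole, in the same order. It is not known whether these are raw or normalized library sizes. A gene of 1 kb at an FPKM of 1 then rests on 15.4, 17.3 and 13.02 fragments, with exact 95% Poisson intervals of 8.66 to 25.2, 10.1 to 27.5 and 6.93 to 22.3. Of 3 fragments, the floor used here, such a gene would have an FPKM of 0.195, 0.174 and 0.230. These intervals and floors cover counting error only.

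Values were analysed as log2(FPKM + 1), which understates differences of genes with low FPKM. Tests used the 13754 genes with a mean FPKM of at least 1. Because there was 1 group, the test asked whether a gene varied between the rats more than genes of its level do. An intercept was fitted per gene with limma (version 3.58.1, R 4.3.3), with a trended and robust prior, whose degrees of freedom were 7.96. Each residual variance was set over its prior variance and compared with the F distribution, one-sided. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

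The test was tested on simulated data for the same 13754 genes. In the simulation of genes variable between rats, 50 genes were seeded at each fold of 1 rat against the others. The folds were of FPKM + 1, so a gene with low FPKM needs a larger fold of FPKM. It recovered 4% of genes at 4-fold, 74% at 16-fold, and 100% at 64-fold and at 256-fold. Of 140 calls in the simulation, 1 was false, but values were drawn independently from the test's own fitted prior, so few false calls were built in. The data gave 14 calls, which makes the adjustment stricter there, so recovery in the data may be lower. Differences of 4-fold are thus mostly outside what the test can call.

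A total of 407 genes in 38 lists were fixed before the data were examined, together with 12 pairs of lists, 20 pairs of genes, the tests and the alternatives. The lists covered reference genes, 13 kinds of cells or tissue components, cortical layers and other regions, injury responses, stress, plasticity, signalling, metabolism and RNA quality. Of the 407 genes, 392 were matched, 2 of them by another symbol, and 15 were not. Where a name stood in more than 1 row, which was so for 7 genes, the row with the higher mean was used. Of the matched genes, 14 were listed at 0 in all rats. A list's level was the median over members in each rat, given as mean and SD over the 3 rats. Its deviation was the median over tested members of the log2 difference from the mean of the rats, set against 10000 random lists matched on mean expression in 20 bins. That comparison describes these libraries and is not a test of a condition. Fisher's exact test, one-sided, asked whether variable genes were over-represented in each list with at least 3 tested members, with Benjamini-Hochberg over 36 lists. It treats members of a list as independent, which they are not. Adjusted p-values were also computed over each list alone. Pair differences were taken within each rat and given an exact two-sided sign-flip test, which with 3 rats cannot go below 0.25.

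The rule for naming genes was fixed in advance. It took, for each list, the 2 members with the highest mean FPKM and up to 2 more, which were members past the variability test by smallest adjusted p and then the member with the lowest mean. It also took both genes of each fixed pair, up to 10 variable genes by range and 10 by adjusted p, and the 10 genes with the highest mean FPKM. Genes outside the rule were named after their values were seen, and the text says so. Results for some genes the rule takes are not reported here.

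Alternatives changed 1 choice at a time, except that leaving out the mitochondrial genome went with rescaling the other genes to a sum of 1000000, which took the genes tested to 15280. They were pseudocounts of 0.1 and 0.5, filters at a mean FPKM of 0.1 and 5 and none, rescaling to a sum of 1000000 (TPM), median-of-ratios scaling, a prior that is not robust, leaving out the mitochondrial genome, a threshold of 0.01, means in place of medians, tested members only, and leaving out each rat. Rescaling to 1000000 moved the median tested gene by 1.00, 1.03 and 0.97 on the log2 scale in rats 12, 24-4 and 33. It thereby also changed the weight of the pseudocount and the reach of the filter, with 14946 genes tested. Median-of-ratios scaling moved it by 0.05, -0.02 and -0.06.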

Results

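Messenger RNA was measured in motor cortex of 3 male rats, numbered 12, 24-4 and 33, all given electroacupuncture after cerebral ischemia and reperfusion, an interruption and return of blood flow to the brain. With 1 group, the data give the level of each gene and its spread between treated animals. The 3 libraries had FPKM sums of 476169, 464587 and 489810 and estimated depths of 15350000, 17260000 and 13020000 fragments in rats 12, 24-4 and 33. At an FPKM of 1 or more, 13611 ± 395 genes (SD, n = 3) were detected per rat, and 12775 genes reached that level in all 3.

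The most abundant transcripts came from the mitochondrial genome, which encodes subunits of the respiratory chain, followed by Ttr and Mbp. Mt-co1 had an FPKM of 14542 ± 2789, Mt-atp8 of 14494 ± 5351, Mt-cox3 of 14354 ± 4997 and Mt-co2 of 10477 ± 4033 (SD, n = 3 rats, here and below unless single rats are given). Mt-nd1 followed at 8832 ± 1369, Mt-cytb at 8241 ± 1636, Mt-nd2 at 7855 ± 3516 and Mt-nd4l at 5516 ± 2508. The other 2 genes among the 10 highest were Ttr, which encodes the thyroid hormone carrier transthyretin, at 5368 ± 6577, and Mbp, which encodes myelin basic protein, at 3821 ± 1569. Mt-nd6, the lowest measured member of the mitochondrial list, had 48.7 ± 6.66. The mitochondrial genome took 26.6% of all FPKM in rat 12, 14.4% in rat 24-4 and 20.9% in rat 33.

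Oligodendrocyte genes had the highest level of the cell lists, followed by astrocyte and neuronal genes. The median of the oligodendrocyte list was 8.40 ± 0.57 on the log2(FPKM + 1) scale, with Mbp at the top and Ermn (78.1 ± 47.1) lowest. Astrocyte genes had a median of 6.18 ± 0.78, led by S100b (750.1 ± 159) and Aldoc (262 ± 27.5), with Aldh1l1 at 7.61 ± 3.95. Genes of glutamatergic neurons had 5.51 ± 0.07, with Nrgn, a calmodulin-binding postsynaptic protein, at 694 ± 282, the vesicular glutamate transporter Slc17a7 at 499 ± 184 and Emx1 at 6.75 ± 3.75. The medians of that list, 5.46, 5.58 and 5.47 in rats 12, 24-4 and 33, hid lower values in rat 33, where 6 of its 7 members were lowest. Genes of GABAergic neurons had 4.40 ± 0.45, with the peptide somatostatin (Sst) at 165 ± 61.1 and the calcium-binding Pvalb at 119 ± 58.7. Npy, a neuropeptide gene of the same list, was listed at 0 in all rats. Microglial genes had 3.98 ± 0.50, with Csf1r at 44.6 ± 23.0 and Siglech listed at 0, 0 and 0.363 in rats 12, 24-4 and 33. Oligodendrocyte precursor genes had 2.52 ± 0.32, with Gpr17 at 38.9 ± 16.1, Pdgfra at 13.9 ± 4.80 and Neu4 listed at 0.

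Vessel genes had lower medians than neuronal, astrocyte and oligodendrocyte genes, and genes of blood leukocytes lay near the floor. The endothelial list had a median of 3.16 ± 0.32, with the tight junction gene Cldn5 at 46.1 ± 14.6, Flt1 at 11.8 ± 1.39 and Kdr at 3.32 ± 1.49. Mural genes had 3.63 ± 0.20, with Rgs5 at 49.7 ± 22.2, Tagln at 45.1 ± 28.1 and Kcnj8 at 2.94 ± 1.19. The fibroblast and meninges list had 3.29 ± 0.89, with Dcn at 14.6 ± 9.01, Col3a1 at 14.4 ± 10.9 and Col1a2 listed at 0 in all rats. Lymphocyte genes had 0.25 ± 0.21 and neutrophil and monocyte genes 0.29 ± 0.06. Of these, the T cell receptor component Cd3e had FPKM values of 0.116, 4.81 and 0.477 in rats 12, 24-4 and 33, Cd8a had 0.620 ± 0.457, and Ms4a1 was listed at 0, 0 and 0.125. Plac8 had 2.86 ± 0.948, Mrc1 had 0.956 ± 0.689 and Mpo was listed at 0. Red blood cell genes had 3.80 ± 1.27, with the haemoglobin genes Hba1 at 187 ± 128 and Hba2 at 89.0 ± 62.3 and Slc4a1 at 0.0936 ± 0.0739.

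Markers of deep cortical layers had a median of 3.31 ± 0.21 and those of upper layers 3.86 ± 0.68. In the deep list Pcp4 had 208 ± 46.6, Fezf2, a regulator of subcerebral projection neurons, had 13.6 ± 7.77 and Foxp2 had 1.65 ± 0.479. In the upper list Lamp5 had 67.7 ± 50.9, Calb1 had 29.3 ± 24.1 and Rspo1 had 3.29 ± 1.11. The striatal list lay at 2.36 ± 0.19, with the dopamine-regulated phosphoprotein gene Ppp1r1b at 79.0 ± 15.8, Penk at 15.6 ± 6.62 and Drd2 at 1.36 ± 0.436. Genes of other brain regions had 1.63 ± 0.34. Among them C1ql2 had 0.859, 8.79 and 12.7 in rats 12, 24-4 and 33, Prox1 had 2.84, 2.35 and 6.86, and Oxt was listed at 0.

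Genes of synapses and receptors for glutamate and GABA were expressed in every rat. The synapse structure list had 7.20 ± 0.44, with Snap25, a component of the vesicle fusion machinery, at 665 ± 445, Syp at 529 ± 188 and Homer1 at 13.6 ± 6.78. Glutamate receptor genes had 4.16 ± 0.13, with Grin1 at 84.0 ± 32.9, Gria2 at 76.8 ± 38.8 and Grin2b at 3.04 ± 2.80. GABA receptor genes had 4.87 ± 0.63, with Gabbr1 at 76.8 ± 18.9 and Gabra3 at 18.5 ± 5.12. Monoamine and acetylcholine receptor genes had 3.05 ± 0.48, with Chrm1 at 51.7 ± 22.9, Chrnb2 at 22.6 ± 7.01 and Adra1a at 1.59 ± 0.917. The opioid, adenosine and neuropeptide list had 1.82 ± 0.37, with Cck at 192 ± 122, Adora1 at 39.7 ± 9.28 and Adora3 listed at 0. Immediate early genes had 3.08 ± 0.74, with Egr1 at 44.7 ± 33.1, Jun at 26.5 ± 7.73 and Npas4 at 0.963 ± 0.899. The trophic factor and axon growth list had 3.59 ± 0.10, with Stmn2 at 168 ± 22.3, the growth cone protein gene Gap43 at 139.9 ± 10.7 and Ntf3 at 0.587 ± 0.265.

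Injury lists spanned a wide range. Complement and MHC genes had 3.59 ± 1.07, with B2m, the light chain of MHC class I, at 274 ± 206, C1qa at 95.7 ± 54.7 and RT1-Bb at 0.696 ± 0.506. Activated microglia and macrophage genes had 3.10 ± 1.60, with Apoe at 1255 ± 356, Tyrobp at 33.5 ± 22.2 and Cst7 listed at 0, 0 and 0.0674. Reactive astrocyte genes had 2.89 ± 1.22, with the intermediate filament genes Gfap at 931 ± 657 and Vim at 184 ± 163, and Steap4 at 0.846 ± 0.351. Interferon response genes had 2.79 ± 1.46, with Ifi27 at 105 ± 74.2, Mx2 at 23.2 ± 27.9 and Oasl at 1.54 ± 1.96. The cytokine, chemokine and inflammasome list had 0.85 ± 0.43, with Tgfb1 at 9.82 ± 4.71, Nfkb1 at 9.69 ± 1.98 and Cxcl2 listed at 0.

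Stress and housekeeping lists had SDs from 0.15 to 0.77. Oxidative stress genes had 4.63 ± 0.27, with the metallothionein gene Mt3 at 350.5 ± 134, Sod1 at 183 ± 18.2 and Srxn1 at 6.31 ± 0.0191. Autophagy and mitophagy genes had 5.43 ± 0.24, with Sqstm1 at 209 ± 47.9, Map1lc3a at 108 ± 29.0 and Atg5 at 7.53 ± 0.485. Hypoxia and vessel growth genes had 4.08 ± 0.15, with Ldha at 143 ± 42.7, the glucose transporter gene Slc2a1 at 58.2 ± 8.59 and Angpt2 at 1.26 ± 0.292. Heat shock and unfolded protein genes had 3.52 ± 0.25, with Atf4 at 135 ± 16.8, Hspa5 at 131 ± 22.1 and Hspa1a listed at 0. Of the 11 measured members of that list, 2 were listed at 0 in all rats and 6 had a mean FPKM of at least 1, which lowers its median. Cell death genes had 2.78 ± 0.48, with the lipid peroxide reductase gene Gpx4 at 202 ± 42.0, Tfrc at 24.2 ± 13.7 and Mlkl at 0.783 ± 0.633. Nuclear genes of oxidative phosphorylation had 7.41 ± 0.33, with Cox4i1 at 560.0 ± 107, Cox6c at 266 ± 8.38 and Ndufs1 at 80.3 ± 13.4. Ribosomal protein genes had 7.20 ± 0.45, with Rpl19 at 366 ± 104 and Rps6 listed at 0. Reference genes had 7.39 ± 0.29, with Actb at 1133 ± 273, Ywhaz at 447 ± 76.6 and Hprt1 listed at 0. The mitochondrial genome list had 12.31 ± 0.77. In all, 22 of the 38 lists had a median above that of the tested genes.

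**Figure D1:**
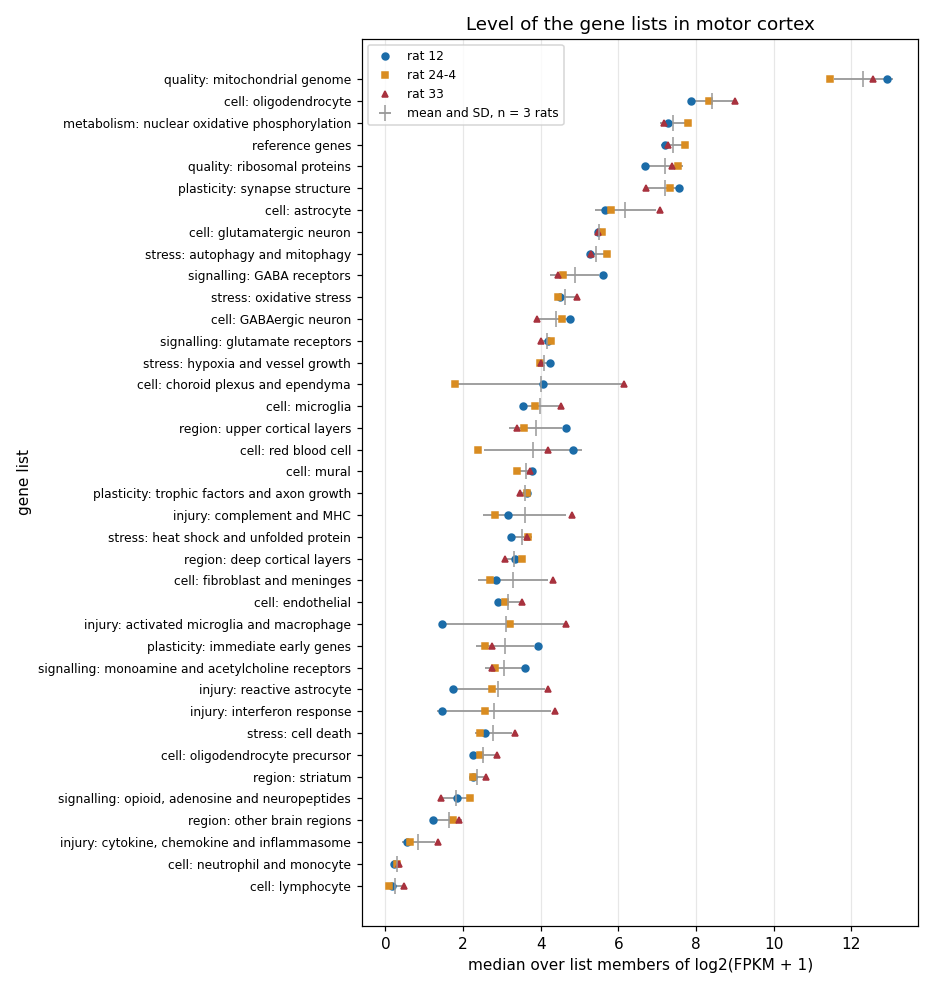
Median log2(FPKM + 1) of each of the 38 gene lists (vertical axis) in rats 12, 24-4 and 33, with the mean and SD over the 3 rats in grey. The lists run from 0.25 for lymphocyte genes to 12.31 for the mitochondrial genome, and the choroid plexus and ependyma list has the widest spread, with an SD of 2.17.

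Within rats, glutamatergic markers exceeded GABAergic ones and mature oligodendrocyte genes exceeded precursor genes. The glutamatergic median was higher than the GABAergic one by 1.11 ± 0.44, and Slc17a7 was higher than Gad1, which makes GABA, by 3.35 ± 0.60. The oligodendrocyte median was above the precursor median by 5.88 ± 0.26, and the astrocyte median was below the oligodendrocyte median, with a difference of -2.22 ± 0.30. General astrocyte markers exceeded those of reactive astrocytes by 3.28 ± 0.54. Microglial markers exceeded lymphocyte markers by 3.73 ± 0.33 and neutrophil and monocyte markers by 3.69 ± 0.44. Against activated microglia and macrophage genes, however, the microglial median differed by 2.10, 0.65 and -0.13 in rats 12, 24-4 and 33. The endothelial minus mural difference was -0.47 ± 0.36, upper minus deep layers was 0.55 ± 0.67, and glutamatergic neuron minus striatum was 3.14 ± 0.23. Complement and MHC genes exceeded cytokine genes by 2.74 ± 0.66, and glutamate receptor minus GABA receptor genes gave -0.72 ± 0.60. Without rat 12, upper minus deep layers was 0.17, endothelial minus mural -0.26, the receptor difference -0.37 and microglia minus activated microglia 0.26. With means over members, upper minus deep layers was 0.30 and its sign was not shared by all rats (exact sign-flip p = 1). The sign was shared by all 3 rats in 11 of the 12 list pairs. The exact sign-flip test gave p = 0.25 for these, the smallest value 3 rats allow, so none could pass 0.05.

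Gene pairs gave the same kind of picture, with 17 of 20 differences of one sign in all rats. Gad1 exceeded Gad2, the other GABA-making enzyme, by 0.18 ± 0.21, and Slc17a7 exceeded Ppp1r1b by 2.60 ± 0.28. Among glia, the difference of the water channel gene Aqp4 minus Mbp was -7.49 ± 0.52, Slc1a2 minus Slc1a3 (glutamate transporters) was 1.81 ± 1.11, Gfap minus Aqp4 was 5.20 ± 0.56 and Gfap minus Vim was 2.39 ± 0.46. Among receptor genes, Grin2a exceeded Grin2b by 1.23 ± 0.34, Oprl1 exceeded Oprm1 by 2.93 ± 0.39 and Adora1 exceeded Adora2a by 3.76 ± 0.30. Bcl2, which restrains apoptosis, minus Bax, which promotes it, was -3.34 ± 0.55. Penk minus Pdyn was 0.66 ± 0.56, Ntrk2 minus its ligand gene Bdnf was 3.93 ± 0.38, Vegfa minus Hif1a was 0.33 ± 0.18 and Egr1 minus Fos was 2.34 ± 0.79. Without rat 24-4, Gad1 minus Gad2 was 0.06 and Penk minus Pdyn 0.38. The sign differed between rats for Pvalb minus Sst (0.22, -0.66 and -1.26 in rats 12, 24-4 and 33), Gria2 minus Gria1 (1.82, -0.30 and 0.54) and P2ry12 minus Spp1 (2.37, -0.49 and -0.54). For P2ry12, a marker of resting microglia, and Spp1, a gene of activated ones, the mean of 0.45 ± 1.67 became -0.52 without rat 12.

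The largest differences between the rats were in genes of the choroid plexus, the epithelium that makes cerebrospinal fluid. Ttr had an FPKM of 3233 in rat 12, 124 in rat 24-4 and 12747 in rat 33. Kl, which encodes the FGF23 coreceptor klotho, had 20.4, 0.106 and 70.6, and the chloride channel gene Clic6 had 21.6, 0.293 and 78.5, in the same order of rats. Of 13754 genes tested with limma, 14 varied more than genes of their level at an adjusted p under 0.05, and 820 had an unadjusted p under 0.05. The call depended on the settings, since 0 genes passed with a prior that is not robust, with a mean FPKM of at least 0.1, without a filter, or with the mitochondrial genome left out and the rest rescaled. In 13 of the 14 the highest value was in rat 33, and in 11 the order was rat 33, rat 12, rat 24-4. Without rat 24-4 no gene passed, while 104 passed without rat 12 and 64 without rat 33, of which 12 and 13 were among the 14. In the same order of settings, 655, 869 and 656 genes had an unadjusted limma p under 0.05. The prior was estimated anew each time, with 3.10, 46.0 and infinite degrees of freedom. The counts with a rat left out therefore do not show which rat carried the variability.

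Ttr (chromosome 18, 15532963 to 15540177) had a limma adjusted p of 0.0492, and Kl (chromosome 12, 943006 to 987551) and Clic6 (chromosome 11, 32655616 to 32699382) each had 0.0170. Other genes with the order of rats 33, 12 and 24-4 were Glycam1 (165, 2.20 and 1.07), Mfrp (131, 27.9 and 0.614), Sostdc1 (132, 23.3 and 1.22), the potassium channel gene Kcnj13 (105, 22.9 and 1.24) and the coagulation factor gene F5 (44.5, 11.5 and 0.138). The bicarbonate transporter gene Slc4a5 (46.3, 9.85 and 0.298), Prr32 (53.0, 11.2 and 0.842) and Tmem72 (38.0, 8.98 and 0.169) had the same order. Their adjusted p-values ran from 0.0170 for Glycam1, Mfrp and Sostdc1 to 0.0420 for Prr32 and Tmem72. Fcrl2, a gene of the Fc receptor-like family, had 0.511, 4.77 and 57.1 in rats 12, 24-4 and 33 (limma adjusted p = 0.0366).

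A histone gene row and an unnamed gene were low only in rat 12. The H3f3b row on chromosome 13 (ENSRNOG00000003220, 99091763 to 99101208) had 1.43, 113 and 153 in rats 12, 24-4 and 33 (limma adjusted p = 0.0170). A further row with the name H3f3b, on chromosome 10 (ENSRNOG00000006532), had 104, 128 and 181. Whether fragments were shared between these rows was not tested, which leaves the first row uncertain. Rn60_10_0890.5 (chromosome 10, 89167135 to 89180160), which carries no symbol and was named after its values were seen, was listed at 0 in rat 12, with 35.1 and 27.7 in the others (limma adjusted p = 0.019996). Vps25 (chromosome 10, 89174684 to 89180160), named after its values were seen, lies within that locus and had 13.4, 3.63 and 5.28 in rats 12, 24-4 and 33. How fragments were divided between these overlapping genes was not tested, which leaves both uncertain.

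**Figure D2:**
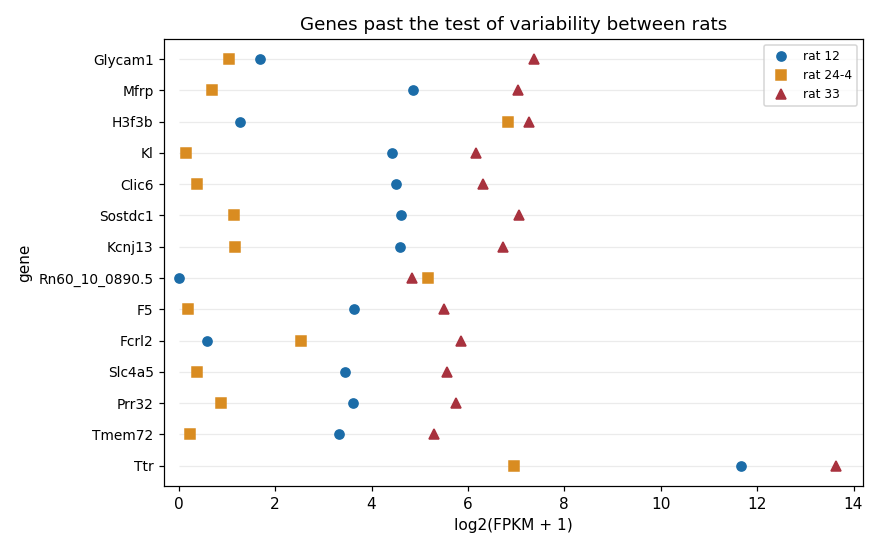
Log2(FPKM + 1) of the 14 genes past the test of variability (vertical axis) in rats 12, 24-4 and 33, 1 point per rat. Rat 33 is highest in 13 of the 14 genes, and 11 have the order rat 33, rat 12, rat 24-4.

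Of the fixed lists, choroid plexus and ependyma held variable genes more often than chance. Its 3 variable genes, Ttr, Clic6 and Kl, were among 7 tested members, where 0.00713 were expected (Fisher's exact test, adjusted p = 1.06e-06 over 36 lists). Adjusted over the list alone, 5 of the 7 passed, with Folr1 (15.5, 2.46 and 69.5 in rats 12, 24-4 and 33) and the water channel gene Aqp1 (10.6, 1.14 and 44.8) joining them. The ependymal genes Tmem212 (1.77, 3.23 and 3.60) and Ccdc153 (3.97, 4.17 and 5.59) passed by neither adjustment. The list had a median of 3.99 ± 2.17, and its deviations from the mean of the rats were 0.15, -2.28 and 2.15. Without rat 24-4, or with a mean FPKM of at least 0.1, no list was enriched. Without rat 12 the interferon list (6 of 13) joined it, and without rat 33 the red blood cell list (4 of 4) did. The changes with a rat left out rest on calls whose prior was estimated anew each time.

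Glial activation, interferon and MHC genes were higher in rat 33 than in rat 12. Irf7, a transcription factor of the interferon response, had 1.75, 7.61 and 37.8 in rats 12, 24-4 and 33, and Mx1, an antiviral GTPase, had 1.63, 4.13 and 43.1. All 13 interferon genes were highest in rat 33, and all 13 passed adjusted over the list alone, but 0 passed over all genes tested. The median deviation of that list was -1.19, -0.38 and 1.63 in rats 12, 24-4 and 33, and the values in all 3 rats lay outside the middle 95% of random lists. Reactive astrocyte genes deviated by -1.22, -0.07 and 1.15, with 8 passing adjusted over the list alone and 0 over all genes. Gfap, one of the 8, had 271, 937 and 1585. Activated microglia and macrophage genes deviated by -1.35, 0.22 and 1.12, with 8 against 0, among them Cd68 (1.73, 8.22 and 24.1) and Spp1 (1.69, 18.7 and 42.1). Complement and MHC genes deviated by -0.67, -0.37 and 0.98, with 7 against 0, among them Cd74 (33.9, 12.9 and 80.8). Irf7, Mx1, Cd68, Cd74, Folr1, Aqp1 and Ccdc153, and genes named below because they passed over a list alone, lie outside the naming rule and were chosen after their values were seen. Choroid plexus genes were also highest in rat 33, but lowest in rat 24-4, as above. Ribosomal protein genes were lower in rat 12 too, with deviations of -0.39, 0.17 and 0.16 and 12 of 13 members lowest in rat 12, and log2(rat 33 / rat 12) fell with locus span across the tested genes (Spearman's rho -0.136).

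General glial lists followed the same direction by less, and neuronal lists the opposite. Deviations in rats 12, 24-4 and 33 were -0.60, 0.00 and 0.72 for microglia, -0.52, -0.06 and 0.63 for oligodendrocytes and -0.43, 0.12 and 0.34 for astrocytes. Fibroblast and meninges genes deviated by -0.48, -0.52 and 1.08, and 3 of them (Col3a1, Col1a1 and Lum) passed adjusted over the list alone, with 0 over all genes. Glutamatergic neuron genes deviated by 0.52, 0.42 and -0.92, below all 10000 random lists in rat 33, and GABAergic ones by 0.18, 0.23 and -0.38. Synapse structure genes deviated by 0.48, -0.19 and -0.51 and GABA receptor genes by 0.57, -0.11 and -0.53. Gabrd and Gabrb2 passed adjusted over the list alone, as did the glutamate receptor genes Grin2a and Grm2, with 0 over all genes in either list. Glutamate receptor genes deviated by 0.22, 0.29 and -0.50, with rat 12 highest in place of rat 24-4 after median-of-ratios scaling, as for the GABAergic list.

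Immediate early genes and upper layer genes were highest in rat 12, and deep layer genes in rat 24-4. Immediate early genes deviated by 0.60, -0.07 and -0.44, with Egr1 at 81.8, 34.2 and 18.2, and none passed over the list alone or over all genes. Upper layer genes deviated by 1.18, -0.29 and -0.49, and Lamp5, Calb1 and Rorb passed adjusted over the list alone, with 0 over all genes. Deep layer genes deviated by 0.00, 0.31 and -0.15. Genes with long loci were also higher in rat 12 than in rat 24-4, with a Spearman's rho of 0.292 across the 13754 genes, which are not independent replicates. Red blood cell genes deviated by 1.05, -1.60 and 0.48, and Hba1, Hba2, Hbb and Hbb-b1 passed adjusted over the list alone, with 0 over all genes. Mitochondrial genes deviated by 0.48, -0.66 and 0.16, and nuclear genes of oxidative phosphorylation by -0.10, 0.27 and -0.18. Adjusted over the list alone, 1 gene passed in each of the other regions (C1ql2), opioid and neuropeptide (Nts) and monoamine (Htr2c) lists, against 0 over all genes. Htr2c had 12.6, 4.71 and 44.8 in rats 12, 24-4 and 33, the order of rats seen for Ttr, Kl and Clic6. Whether it shared a source with these choroid plexus genes was not tested. Cd3e was the only tested member of the lymphocyte list, so its p of 0.00720 there is unadjusted, and over all genes it had 0.508. By either adjustment, 0 genes passed in the reference, mitochondrial genome, ribosomal protein, oxidative phosphorylation, trophic factor, synapse, deep layer, cytokine and stress lists. The same held for the lists of glutamatergic and GABAergic neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, and neutrophils and monocytes.

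**Figure D3:**
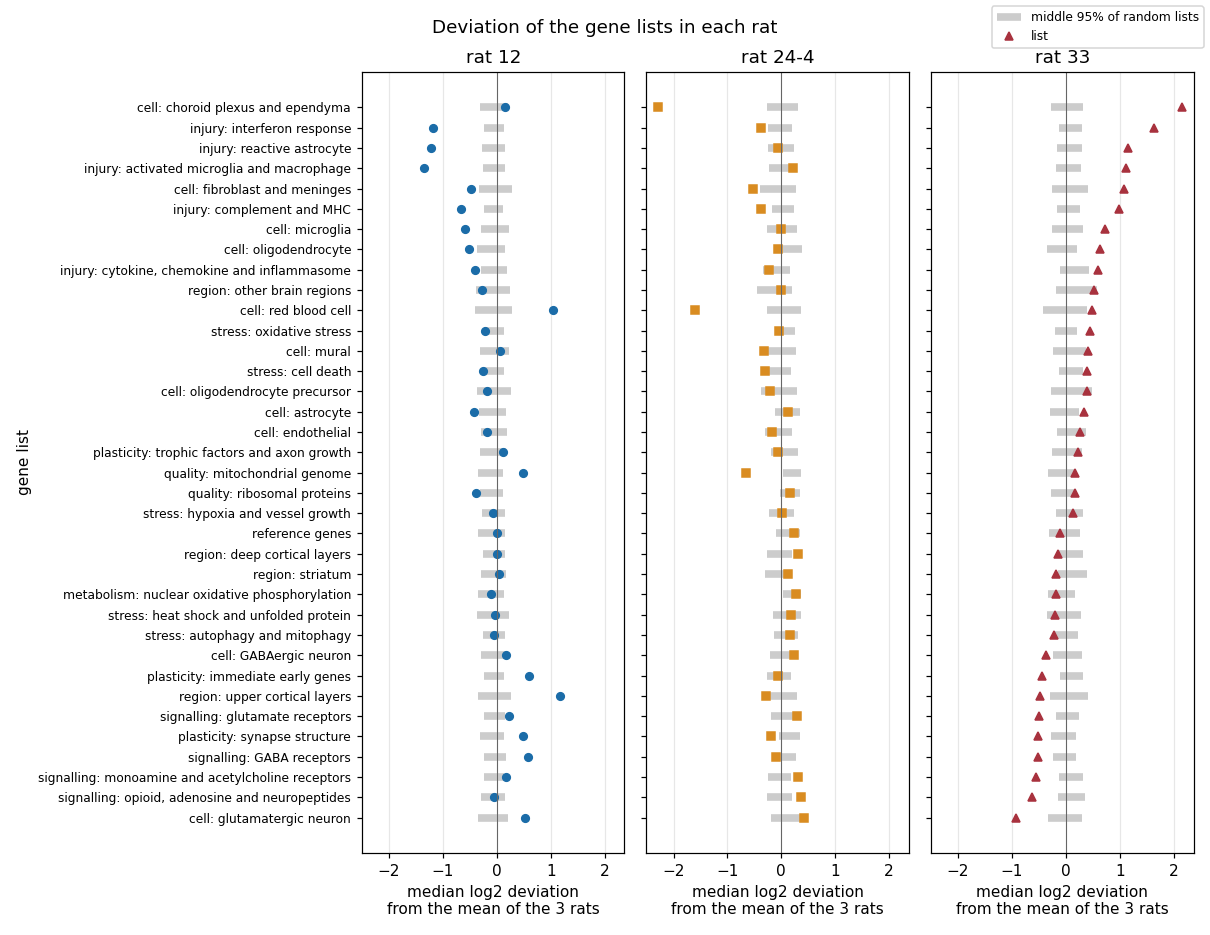
Median log2 deviation of each of 36 gene lists from the mean of the 3 rats (horizontal axis), 1 panel per rat, with the middle 95% of 10000 matched random lists as grey bars. In rat 33, 14 lists lie above the bars and 11 below. On each side 0.9 would be expected if genes and lists varied independently, which they do not.

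By correlation across genes and by the share within 2-fold, rats 12 and 24-4 were closest, but not by the median absolute log2 difference, which was 0.36 for them, 0.35 for rats 12 and 33 and 0.41 for rats 24-4 and 33. Pearson's r of log2(FPKM + 1) was 0.950 for that pair, 0.919 for rats 12 and 33, and 0.921 for rats 24-4 and 33, with Spearman's rho of 0.944, 0.911 and 0.912. Within 2-fold lay 94.3%, 86.9% and 88.5% of the tested genes. Of 1807 genes that differed over 2-fold between rats 12 and 33, 1226 were higher in rat 33. Rat 33 was thus involved in both of the larger sets, the other being 1583 genes against rat 24-4.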

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

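All alternatives in this part were planned before the data were examined. The count of 14 variable genes depended on nearly every choice. It was 23 with a pseudocount of 0.1 and 14 with 0.5, 25 after rescaling to 1000000, 19 with a mean FPKM of at least 5 and 8 with median-of-ratios scaling. It was 0 with a mean FPKM of at least 0.1, without a filter, with a prior that is not robust, at a threshold of 0.01, and with the mitochondrial genome left out and the rest rescaled to 1000000, which changed 2 choices together. Among these settings of 0, limma gave from 729 to 903 genes with an unadjusted p under 0.05. Leaving out each rat gave counts from 0 to 104. The 14 genes kept their call in 89 of 168 cases and lost it in 79. Apart from the threshold of 0.01, settings without calls had a prior with 3.10 to 6.66 degrees of freedom. All settings with calls had 7.47 or more. The calls thus went with the estimated prior, whose degrees of freedom were not varied by themselves. The count of enriched lists, 1, became 0 with a mean FPKM of at least 0.1 and ranged from 0 to 2 when each rat was left out. Pearson's r between rats 12 and 33, 0.919, was 0.957 without a filter, where more low genes enter. It was 0.880 with a mean FPKM of at least 5, where fewer do. The P2ry12 minus Spp1 difference turned to -0.52 without rat 12 and ranged up to 0.94 over the rats left out, while the means of all other differences of lists and genes kept their sign, though several shrank without rat 12, such as upper minus deep layers from 0.55 to 0.17. The count of lists above the median gene stayed between 19 and 24. Levels of lists moved by more than the SD in 60 of 304 cases, 32 of them after rescaling to 1000000. The order of rats by list deviation kept its highest rat in 33 of 36 lists with median-of-ratios scaling and its lowest in 35. At 13020000 to 17260000 fragments, a gene of 1 kb cannot be told from 0 below an FPKM of about 0.230 in rat 33, and the simulation recovered 4% of genes that differed 4-fold in FPKM + 1 in 1 rat.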

Other observations

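The tests of the choroid plexus and the glial patterns, and all genes named in this part, were chosen after the values were seen, while the hippocampal marker lists and their tests were written before those markers' values were read. Some genes outside the fixed interferon list, picked by hand and not tallied, were highest in rat 33. Slfn3 had an FPKM of 1.25, 1.96 and 32.0 in rats 12, 24-4 and 33, Usp18 had 1.56, 3.84 and 20.3, Rtp4 had 1.11, 2.40 and 14.7, and Ifi44 had 1.71, 2.08 and 12.1. Lgals3bp had 12.3, 20.6 and 103. The growth factor gene Mdk had 61.3, 29.7 and 299, so it was lowest in rat 24-4, as the choroid plexus genes were. The class I gene RT1-A2, already a member of the fixed complement and MHC list, had 9.505, 10.1 and 87.5. None of these passed the limma test over all genes, with adjusted p-values from 0.0977 for Slfn3 to 0.483 for Ifi44.

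Several neuronal genes were lowest in rat 33 without passing the limma test. Mef2c, a transcription factor of excitatory neurons, had 41.0, 18.7 and 3.99 in rats 12, 24-4 and 33 (adjusted p = 0.202), Scn4b had 60.03, 34.0 and 6.83 (0.213) and Syt2 had 37.8, 19.5 and 3.40 (0.182). Wfs1 had 41.3, 191 and 13.2 (adjusted p = 0.148), and Nts had 0.901, 13.5 and 0.168 (0.174).

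Choroid plexus genes differed between rats, and the tables argue against library scaling, with size factors at most 0.12 apart on the log2 scale, while the 5 epithelial genes of the fixed list were higher in rat 33 than in rat 12 by 1.79 to 2.16. Blood is argued against for that excess, since haemoglobin genes went the other way, with a median of -0.64 over 4 genes. It stays open for the low values of rat 24-4, where haemoglobin was lowest too. Between rats 12 and 24-4 haemoglobin genes differed by 2.69 to 3.22 and the choroid genes by 2.66 to 7.59, with a median of 4.71. Of the 5 choroid genes, 3 exceeded every haemoglobin gene. Choroid plexus carried into the dissected cortex in differing amounts, which may bring its transcripts in one ratio, stays open. Between rats 12 and 24-4 the 5 genes as measured were not in one ratio. Kl, near the floor in rat 24-4 at 0.106 FPKM, gave the highest difference, which is uncertain for that reason. Folr1, at 2.46 in rat 24-4, gave the lowest, and Ttr, at 124, gave the median. The SD of the 5 differences between rats 33 and 12 was 0.15, at the 5.02 percentile of 994664 random sets of genes over 2-fold higher in rat 33, against a limit of 5. A first run of 10000 draws fell just under that limit, so more draws were taken and clearing the limit by the simulation error was required, and no biological explanation was tested because there was 1 group.

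Reactive astrocyte, activated microglia, interferon, and complement and MHC lists were highest in rat 33. Choroid tissue alone would make them higher in rat 12 than in rat 24-4, but over 33 members of the first 3 lists the median was -1.01 (95% bootstrap interval over genes -1.43 to -0.59). This argues against choroid tissue as the only source of the order of rats in those lists, while a share of it in the excess of rat 33 was not tested. Over the 14 complement and MHC genes the median was -0.24 (-0.996 to 0.39), which leaves choroid tissue open for that list. A lower share of neurons in rat 33 would raise injury genes as much as markers of glia and vessels. Over all 5 injury lists the excess in rat 33 was larger by 0.87 (95% bootstrap interval over genes 0.62 to 1.14). The list deviations given above had already shown this gap, so the value describes rat 33 and is no separate test. The filter on mean FPKM could also let in genes through rat 33, since 10 of the 13 interferon genes reached an FPKM of 1 in all rats. A lower share of neurons as part of the pattern thus stays open. Blood would need more haemoglobin in rat 33 than in rat 12, but its 4 genes had a median of -0.64, which does not speak to leukocytes that entered the tissue. A trend with locus span was too small by itself to give this pattern. Over 20 bins of span, the median log2(rat 33 / rat 12) of tested genes ran from -0.17 to 0.28. The 47 members of the 4 lists had a median of 2.20 (95% bootstrap interval over genes 1.86 to 2.54). Subtracting bin medians of that size could not have removed the excess, which became 2.02 (1.67 to 2.38). A difference between the animals in RNA quality, in the extent of the lesion or in the part of the cortex taken could also give this pattern and was not tested.

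Hippocampal tissue in the dissected cortex is a candidate explanation for Wfs1 and Nts in rat 24-4 and C1ql2 in rats 24-4 and 33, though the dentate marker Prox1, with 2.84, 2.35 and 6.86 in rats 12, 24-4 and 33, was lower in rat 24-4 than in rat 12. Of 11 markers of the hippocampal CA fields, 6 could be tested, and their median in rat 24-4 against the others was -0.092, at the 35.6 percentile of random lists, with 2 above 0. Of 9 dentate gyrus markers, 6 could be tested, and their median in rats 24-4 and 33 against rat 12 was 0.30, at the 87.1 percentile, with 4 above 0. The bound written beforehand, a median below 0, was met for the CA fields by less than the spread of the markers (95% bootstrap interval -0.80 to 0.69), and a requirement to exceed that spread was added after the value was seen. With so few markers measured, which cortex may also express, the most abundant of them Cpne7 at 13.4, 29.7 and 75.3 in rats 12, 24-4 and 33, the explanation can be neither kept nor set aside.

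Some genes were near 0 in 1 rat and abundant in the others. By a rule set after seeing the values (lowest at most 2, next at least 10, other 2 within 2-fold), there were 4, namely Fam111a (0.224, 14.3 and 14.9 in rats 12, 24-4 and 33), Rpl35a on chromosome 1 (14.4, 11.5 and 0.221), and the H3f3b row and Rn60_10_0890.5 described above. RT1-CE16, in the MHC region of chromosome 20, had 0, 22.2 and 0.0661, and Rps2-ps2 on the same chromosome had 0, 19.0 and 0. Between rats 12 and 24-4 the median log2 difference was -0.26 over the 25% of tested genes with the shortest loci and 0.18 over the 25% with the longest.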
